A study of Antheraea pernyi with 6 samples.

How the data were processed

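Antennae of adult Antheraea pernyi, the Chinese oak silkmoth, were profiled by mRNA sequencing in 6 libraries, 3 labelled female and 3 labelled male. RNA was extracted with Trizol and libraries were made with a strand-keeping mRNA kit, per the labels' protocols. Nothing in the labels says whether libraries of a sex came from separate animals, so p-values of the gene tests measure the spread between these libraries, which may be technical in part.

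The deposited table gives FPKM per gene for the 6 libraries, with a best protein hit, a gene symbol and pathway names that the authors added. Trimmomatic, HISAT2, HTSeq and R 3.2.0 are named in the submitters' processing notes, without their roles. The genome build and the annotation version are not given in the sources used here, so no coordinates are printed and genes carry the identifiers and best-hit names of the deposited table. Best-hit names come from other species in many cases, and reads of near-identical copies in gene families such as cuticle proteins, attacins, defensins and odorant receptors could have been split between copies by the authors' counting.

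The deposited FPKM values kept the steps of whole reads. A search over gene lengths and library totals gave whole reads, within a tolerance of 0.01 read, for 16458 of 16458 genes in all 6 libraries (100% of genes). The search took the shortest length of at least 90 bases that gave whole reads. Where the counts of a gene share a factor, its reads and length can therefore be too low by that factor. Ratios between sets with reads stay the same, while their intervals come out too wide. Ratios against a floor come out too low, and shares of reads pooled over genes could shift. The totals came to 11030594, 11180175 and 10851262 reads for replicates 1, 2 and 3 labelled female and to 9392242, 9606755 and 9450113 for those labelled male. Of the lengths of the 11340 genes with more than 30 reads, 87.9% were multiples of 3, so they are called coding lengths. Libraries of 1 sex differed from each other by more than read sampling, with a chi-square per gene between 3.08 and 3.99, so they are not the same library read again, which does not show whether they came from separate animals.

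Genes with a mean FPKM of at least 0.5 were tested (11590 of 16458) with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1) with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Sex was the only term, tests were 2-sided, and log2 fold changes are the libraries labelled male minus those labelled female. On the log2(FPKM + 1) scale the change of low genes is understated. The 27 gene lists were written as patterns on names or symbols before the data were examined, as were the main test, the alternatives not marked as added below and the rule for named genes. Wrong matches (138 in all) were taken out of the lists after names and some fold changes had been seen, and lists with them are among the alternatives. Lists with at least 5 tested members (25 lists) were compared with all other genes, in their changes between labels, by camera with a preset correlation of 0.01. Camera p-values thus rest on the spread of changes across genes and on that correlation, not on the spread between libraries alone. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the members of a list move on balance 1 way, without comparing them with other genes. Pathway names of the deposited table with 10 to 300 tested genes were tested by camera in the same way (303 pathways).

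Named genes followed a fixed rule. It took the 10 largest changes each way among named genes past the test, with all libraries of a label above all of the other and a mean of at least 5 FPKM in the higher set. It added the 2 largest changes each way in every list, and the most abundant member of a list with none past the test. Whatever their values, it took the odorant receptor coreceptor, pheromone-binding and general odorant-binding proteins, sensory neuron membrane proteins, doublesex, fruitless and period. The genes printed are a part of those the rule took. They were picked after their values were seen, and list members whose call was lost without single libraries were mostly left out. Genes named outside the rule are marked as chosen after their values were seen. A ratio against a set with no reads was computed against a floor of 3 reads over the set, and other ratios of few reads have exact 95% intervals, both of which cover counting error only.

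Shares of total FPKM were compared by 2-sided exact permutation tests over 30 comparisons, for which 3 libraries against 3 allow no p below 0.1. The limma step was checked on simulated counts for these genes and library sizes, with 200 genes drawn as changed and a dispersion of 0.01. Of 11584 simulated genes tested, it found 26.9% of 67 genes changed 1.5-fold, 68.2% of 66 changed 2-fold and 84.4% of 64 changed 4-fold, with 6 false calls. Simulated changes went both ways with no shift of the median gene, so the false calls do not cover error from scaling. The dispersion was set rather than estimated from these libraries, so the shares found and the false calls need not describe the real fit. Alternatives covered the pseudocount, the filter, 3 rescalings, the trend, robust moderation, a replicate block, each library left out, the fold threshold and the list tests. Added after seeing the data were limma-voom on the recovered reads, removal of a trend on coding length (lowess span of 0.3), and 2 other versions of the lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the remaining steps.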

Results

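The antenna is the main olfactory organ of Antheraea pernyi, a silkmoth in which males locate females by a sex pheromone. FPKM values of 16458 genes were compared between 3 antennal libraries labelled female and 3 labelled male. Library totals lay between 9392242 and 11180175 reads, as recovered from the steps of the FPKM values. Groups are named by their labels throughout. Genes of pheromone-binding proteins 1 and 3, members of a family often male-biased in moths, were highest in the female-labelled libraries, and genes named for females had reads in the male-labelled libraries alone. Those were 49 reads over 4 genes, and most reads of genes named for males lay in the male-labelled libraries too (67.6%, corrected for library totals). Exchanged labels and a true sex difference could not be told apart. Every direction below is therefore one between labels, and where values are given as one against another the female-labelled mean stands first.

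Libraries separated by label. Pearson correlations of log2(FPKM + 1) across 11590 genes lay between 0.9844 and 0.986 within a label and between 0.9502 and 0.952 across labels. The first principal component held 69.2% of the variance and the next 7.9%. These correlations are across genes, which are not independent replicates.

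Among named genes past the test, the 10 largest changes each way ranged from -9.95 to -4.87 and from 4.04 to 5.94 in log2 fold change. Olfactory receptor 1 (GWHGABGR000138) stood at 1140.3 ± 34.6 FPKM (SD, n = 3) in the female-labelled libraries and 0.176 ± 0.305 in the male-labelled ones (log2 fold change -9.95, SE 0.16, limma adjusted p = 9.92e-10). Pheromone-binding protein 1 (GWHGABGR012196), a soluble carrier of pheromone in the sensillum lymph, stood at 92516 ± 2089 FPKM (SD, n = 3) in the female-labelled libraries and 1273 ± 90.6 in the male-labelled ones (log2 fold change -6.18, SE 0.05, limma adjusted p = 3.33e-11). In the other direction, a lebocin-like antimicrobial peptide gene (GWHGABGR010289) stood at 25.2 ± 7.06 FPKM (SD, n = 3) in the female-labelled libraries and 1575 ± 25.8 in the male-labelled ones (log2 fold change 5.94, SE 0.15, limma adjusted p = 1.57e-08). A lipase member H-A-like gene (GWHGABGR017979) stood at 1.46 ± 0.0817 against 67.9 ± 4.41 FPKM (log2 fold change 4.81), and neuropeptide F receptor-like (GWHGABGR018783) at 69.6 ± 7.13 against 0.548 ± 0.27 FPKM (log2 fold change -5.52).

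Of 11590 genes tested, 4274 (36.9%) passed limma at an adjusted p of 0.05. On the deposited scale 3227 of them were higher in the male-labelled libraries and 1047 in the female-labelled ones. This split depended on the scaling. The median log2 fold change of all tested genes was 0.23 on the deposited scale and 0.02 after median-of-ratios rescaling, which called 1652 and 2040 genes. Quantile normalization called 1636 and 1688. Of the 4274 genes, 2699 were called with the same sign after median-of-ratios rescaling and 17 with the opposite sign. List medians are to be read against 0.23, and counts after rescaling stand beside those on the deposited scale.

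Soluble carriers of odorants moved both ways. Pheromone-binding protein 1 and pheromone binding protein 3 (GWHGABGR012195, 11729 ± 248 against 1082 ± 28 FPKM, log2 fold change -3.44, limma adjusted p = 3.33e-11) were higher in the female-labelled libraries. General odorant-binding protein 1 (GWHGABGR012186, 5239 ± 133 against 10391 ± 124 FPKM, log2 fold change 0.99) was higher in the male-labelled libraries. So was general odorant-binding protein 2 (GWHGABGR012194, 11568 ± 297 against 17546 ± 789 FPKM, log2 fold change 0.60). Of 18 tested odorant-binding proteins, 12 were higher in the male-labelled libraries and 3 in the female-labelled ones. The odorant-binding proteins gave 12 and 4 when adjusted over the list alone, and 7 and 4 after median-of-ratios rescaling. Their median was 0.38 and their mean -0.31, and camera, which gave the direction of the median, did not pass (adjusted p = 0.517). Among the other general odorant-binding proteins, log2 fold changes were 0.45 for 28a-like (GWHGABGR014087), 0.75 for 72-like (GWHGABGR014091) and 0.93 for 70 (GWHGABGR004634), all past the test with and without rescaling. Calls were lost after median-of-ratios rescaling for 67-like (GWHGABGR003120, 0.37), 19a-like (GWHGABGR014090, 0.50) and a gene with a pheromone binding protein 1 hit (GWHGABGR012197, 0.39). General odorant-binding protein 56a (GWHGABGR017175) lay at 0.00, and at -0.26 after that rescaling, while 19d-like (GWHGABGR014092, -0.22) did not pass.

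Chemosensory proteins, small soluble carriers of another fold, were mostly higher in the male-labelled libraries by gene. Of 11 tested chemosensory proteins, 7 were higher in the male-labelled libraries and 2 in the female-labelled ones. The chemosensory proteins gave 7 and 2 when adjusted over the list alone, and 6 and 2 after median-of-ratios rescaling. Chemosensory protein 8 (GWHGABGR001111) stood at 10.4 ± 1.09 against 32.8 ± 4.72 FPKM and another chemosensory protein gene (GWHGABGR012364) at 198 ± 10.8 against 54.5 ± 7.36 FPKM. As a list they had a median of 1.10 and did not pass camera (adjusted p = 0.0692), and passed after median-of-ratios rescaling (adjusted p = 0.0143; 0.0116 to 0.195 over all camera alternatives run). They also passed without female replicate 1 (0.0471), without female replicate 3 (0.0437) and without male replicate 3 (0.0441).

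Odorant receptors also moved both ways. A putative odorant receptor (GWHGABGR021060) stood at 263 ± 3.79 against 0.502 ± 0.279 FPKM (log2 fold change -7.47), and a partial olfactory receptor 20 (GWHGABGR011421) at 37.8 ± 2.27 against 0.362 ± 0.364 FPKM (log2 fold change -4.87). Olfactory receptor 1 had 14852 reads in the female-labelled libraries and 2 in the male-labelled ones, a ratio of 6389.9 corrected for library totals (exact 95% interval 1769 to 52768). Its recovered length of 394 bases is not a multiple of 3, so both counts may be too low by a common factor. In the other direction, a partial odorant receptor (GWHGABGR013978) had 119 reads in the male-labelled libraries and 0 in the female-labelled ones. It was at least 46.1-fold higher, against a floor of 3 reads over the group. Another odorant receptor (GWHGABGR010755) stood at 0.692 ± 0.62 against 19.9 ± 1.76 FPKM. Of 44 tested odorant receptors, 17 were higher in the male-labelled libraries and 11 in the female-labelled ones. The odorant receptors gave 19 and 11 when adjusted over the list alone, and 12 and 11 after median-of-ratios rescaling. Their median was 0.50 and their mean -0.13, and camera, which gave the direction of the mean, did not pass (adjusted p = 0.421).

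The odorant receptor coreceptor Orco, which forms channels with odorant receptors, is listed as putative chemosensory receptor 2 (GWHGABGR013501, with the mosquito Orco identifier AGAP002560 as symbol), a name outside the list pattern. It stood at 465 ± 5.9 FPKM (SD, n = 3) in the female-labelled libraries and 176 ± 1.58 in the male-labelled ones (log2 fold change -1.40, SE 0.04, limma adjusted p = 1.43e-08). Of 4 tested genes in the list of sensory neuron membrane proteins, 2 of them matched by description, 0 were higher in the male-labelled libraries and 3 in the female-labelled ones. The sensory neuron membrane proteins gave 0 and 3 when adjusted over the list alone, and 0 and 3 after median-of-ratios rescaling, with a median of -0.53, and were too few for camera. Sensory neuron membrane protein 2 (GWHGABGR005182) stood at 3042 ± 5.49 against 2427 ± 41.4 FPKM. The other called genes are in the list by the symbol Snmp-1 alone, so they may not belong to the family. The best hit of GWHGABGR014195 (56.2 ± 1.06 against 18.4 ± 1.15 FPKM) is xanthine dehydrogenase-like. That of GWHGABGR014193 (13.5 ± 0.223 against 7.81 ± 1.32 FPKM) is a hypothetical protein. Another sensory neuron membrane protein 2 (GWHGABGR000255, 0.654 ± 0.25 against 0.647 ± 0.34 FPKM) did not pass. Of 19 tested ionotropic receptors, 7 were higher in the male-labelled libraries and 3 in the female-labelled ones. The ionotropic receptors gave 8 and 3 when adjusted over the list alone, and 6 and 5 after median-of-ratios rescaling, with a median of 0.68 and a camera adjusted p of 0.699. Ionotropic receptor 93a was higher in the female-labelled libraries in both of its models (GWHGABGR021126, 19.1 ± 0.686 against 6.01 ± 2.64 FPKM, and GWHGABGR005160, 40.6 ± 4.75 against 15.6 ± 0.966 FPKM), and ionotropic receptor 21a (GWHGABGR021191, 0.792 ± 0.775 against 4.24 ± 0.969 FPKM) in the male-labelled ones. The 1 gustatory receptor tested (GWHGABGR011828) did not pass (1.7 ± 1.98 against 1.51 ± 1.62 FPKM).

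**Figure D1:**
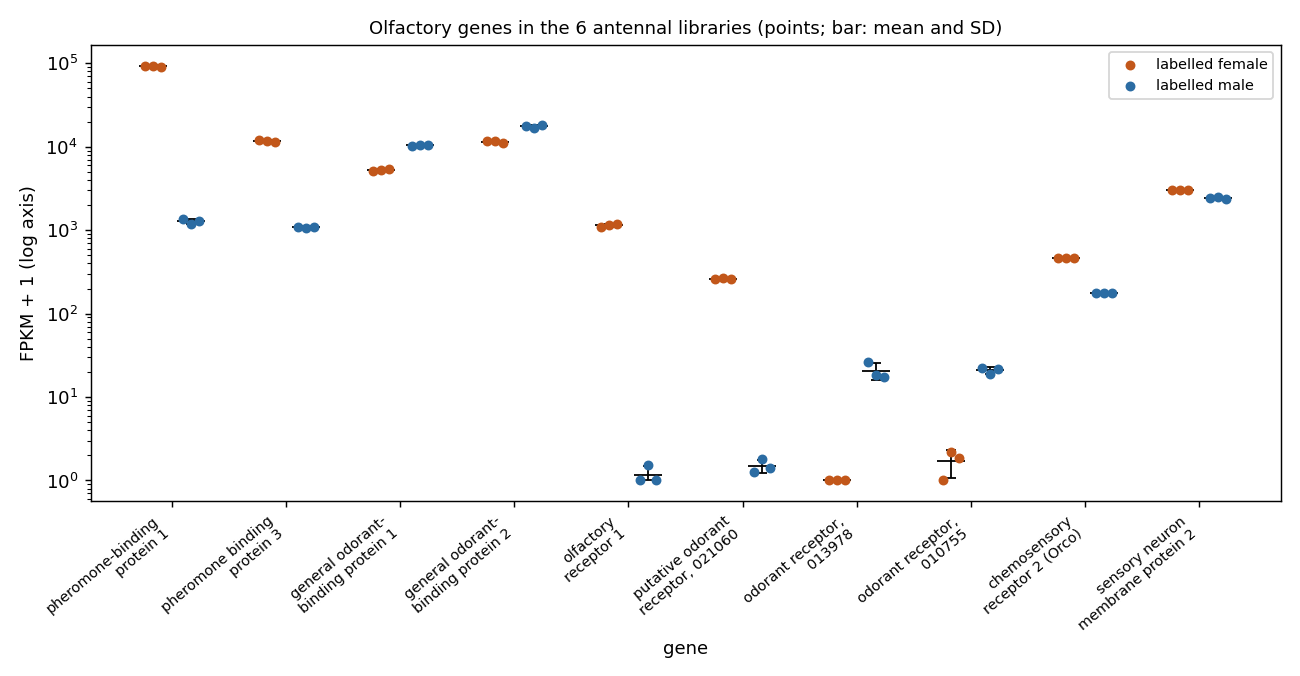
FPKM + 1 on a log axis for 10 olfactory genes, with a point per library, a bar at the mean and whiskers of 1 SD that end at 0 FPKM, for 3 libraries labelled female and 3 labelled male. Pheromone-binding protein 1 lies at a mean of 92516 FPKM in the female-labelled libraries and 1273 in the male-labelled ones, while general odorant-binding protein 1 lies at 5239 and 10391.

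Glutathione S-transferases, an enzyme family that can degrade odorants, were lower in the male-labelled libraries relative to other genes. A glutathione S-transferase 2-like gene (GWHGABGR016653) stood at 1417 ± 7.79 FPKM (SD, n = 3) in the female-labelled libraries and 47.9 ± 1.98 in the male-labelled ones (log2 fold change -4.86, SE 0.04, limma adjusted p = 4.49e-11). Another 2-like gene (GWHGABGR016652) stood at 63.8 ± 31.3 against 2.09 ± 1.86 FPKM, and glutathione S-transferase delta (GWHGABGR012607) at 6.46 ± 0.534 against 14.8 ± 1.51 FPKM. Of 19 tested glutathione S-transferases, 3 were higher in the male-labelled libraries and 10 in the female-labelled ones. The glutathione S-transferases gave 4 and 10 when adjusted over the list alone, and 1 and 12 after median-of-ratios rescaling. Their median was -0.46 (camera adjusted p = 7.88e-06, and adjusted p = 0.0395 with an estimated correlation). Of 23 tested UDP-glycosyltransferases, 12 were higher in the male-labelled libraries and 1 in the female-labelled ones. The UDP-glycosyltransferases gave 13 and 1 when adjusted over the list alone, and 7 and 2 after median-of-ratios rescaling. Among them UDP-glucuronosyltransferase 2B2-like (GWHGABGR006272) stood at 9.35 ± 2.01 against 52.5 ± 7.51 FPKM and 2B15-like (GWHGABGR013102) at 35.4 ± 3.54 against 8.67 ± 1.19 FPKM. This list had a median of 0.34 and lay above other genes by camera (adjusted p = 0.0325, and adjusted p = 0.183 with an estimated correlation). Its call was also lost with a mean FPKM of at least 2 (adjusted p = 0.0578), without female replicate 2 (adjusted p = 0.0613), and without male replicate 2 (0.0648; 0.0145 to 0.183 over all camera alternatives run).

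Aldehyde and alcohol enzymes moved both ways. An aldehyde dehydrogenase (GWHGABGR014228) stood at 24.8 ± 1.33 against 2.2 ± 0.116 FPKM, and a xanthine dehydrogenase/oxidase (GWHGABGR014201) at 10.8 ± 0.858 against 30.9 ± 1.68 FPKM. Of 32 tested aldehyde oxidases and aldehyde or alcohol dehydrogenases, 10 were higher in the male-labelled libraries and 9 in the female-labelled ones. These aldehyde and alcohol enzymes gave 10 and 9 when adjusted over the list alone, and 6 and 11 after median-of-ratios rescaling. Their median was 0.07, their mean -0.06 and their median after rescaling -0.17. Camera placed them below other genes (adjusted p = 0.0325, and adjusted p = 0.153 with an estimated correlation). That call was lost after median-of-ratios rescaling (adjusted p = 0.1), with quantile normalization (0.128) and with no filter on low values (0.0923). It was also lost with a replicate block (adjusted p = 0.0515) and without female replicate 2 (0.0516; 0.0278 to 0.153 over all camera alternatives run).

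Pheromone-degrading enzyme 1 (GWHGABGR011087), an esterase, stood at 0.487 ± 0.243 FPKM (SD, n = 3) in the female-labelled libraries and 9.44 ± 0.833 in the male-labelled ones (log2 fold change 2.82, SE 0.19, limma adjusted p = 9.81e-06). Of 30 tested carboxylesterases, 13 were higher in the male-labelled libraries and 2 in the female-labelled ones. The carboxylesterases gave 13 and 3 when adjusted over the list alone, and 11 and 5 after median-of-ratios rescaling. As a list they did not pass camera (adjusted p = 0.067) and passed after median-of-ratios rescaling (0.0339; 0.0209 to 0.335 over all camera alternatives run). They also passed without female replicate 1 (adjusted p = 0.0497), without female replicate 3 (0.0437) and without male replicate 3 (0.046). Cytochrome P450 4c21-like (GWHGABGR009093) stood at 153 ± 1.42 against 639 ± 22.9 FPKM (log2 fold change 2.05). Of 52 tested cytochrome P450 genes, 20 were higher in the male-labelled libraries and 3 in the female-labelled ones. The cytochrome P450 genes gave 20 and 3 when adjusted over the list alone, and 15 and 9 after median-of-ratios rescaling, with a camera adjusted p of 0.323.

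Immune genes were higher in the male-labelled libraries. A gloverin-like antimicrobial peptide gene (GWHGABGR020678) stood at 18.2 ± 2.5 FPKM (SD, n = 3) in the female-labelled libraries and 827 ± 15.5 in the male-labelled ones (log2 fold change 5.44, SE 0.09, limma adjusted p = 9.92e-10). A further lebocin-like gene (GWHGABGR010288) stood at 6.74 ± 1.42 against 194 ± 9.16 FPKM and a gallerimycin-like gene (GWHGABGR005400) at 24.4 ± 4.71 against 547 ± 48.1 FPKM. In the other direction, beta-1,3-glucanase (GWHGABGR008234) stood at 108 ± 1.21 against 26.4 ± 1.27 FPKM. Of 71 tested hemocyte markers and immune genes, 50 were higher in the male-labelled libraries and 8 in the female-labelled ones. The immune genes gave 52 and 8 when adjusted over the list alone, and 42 and 9 after median-of-ratios rescaling. Their median was 0.77 (camera adjusted p = 1.78e-08, and adjusted p = 0.0182 with an estimated correlation). Among 10 hemocyte markers, a part of the list set apart after seeing the data, 7 passed, all higher in the male-labelled libraries, with a median of 0.63, and 5 of them passed after median-of-ratios rescaling. Of 37 tested fat body and hemolymph proteins, 18 were higher in the male-labelled libraries and 2 in the female-labelled ones. The fat body and hemolymph proteins gave 18 and 2 when adjusted over the list alone, and 12 and 2 after median-of-ratios rescaling. Camera did not pass for them (adjusted p = 0.0842) and passed after median-of-ratios rescaling (0.0331; 0.0331 to 0.237 over all camera alternatives run). Most called members went toward the label male, such as a moderately methionine rich hexamerin (GWHGABGR009147, 0.836 ± 0.412 against 5.01 ± 1.2 FPKM). Apolipophorin-III (GWHGABGR013340), a lipid carrier of the hemolymph, stood at 543 ± 17.7 against 410.1 ± 7.39 FPKM.

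Cuticle genes were higher in the female-labelled libraries. Cuticle protein 7-like GWHGABGR004573 stood at 234 ± 8.51 FPKM (SD, n = 3) in the female-labelled libraries and 0.358 ± 0.621 in the male-labelled ones (log2 fold change -7.53, SE 0.26, limma adjusted p = 1.12e-07). GWHGABGR004572 (333 ± 12.9 against 1.58 ± 0.881 FPKM) and GWHGABGR004575 (405 ± 25.9 against 2.35 ± 0.951 FPKM) carry the same name. In the other direction, a putative cuticle protein (GWHGABGR004501) stood at 7.39 ± 0.753 against 61.9 ± 4.58 FPKM. Of 111 tested cuticle genes, 23 were higher in the male-labelled libraries and 63 in the female-labelled ones. The cuticle genes gave 26 and 65 when adjusted over the list alone, and 13 and 68 after median-of-ratios rescaling. Their median was -0.84 (camera adjusted p = 9.21e-20, and adjusted p = 0.0182 with an estimated correlation).

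**Figure D2:**
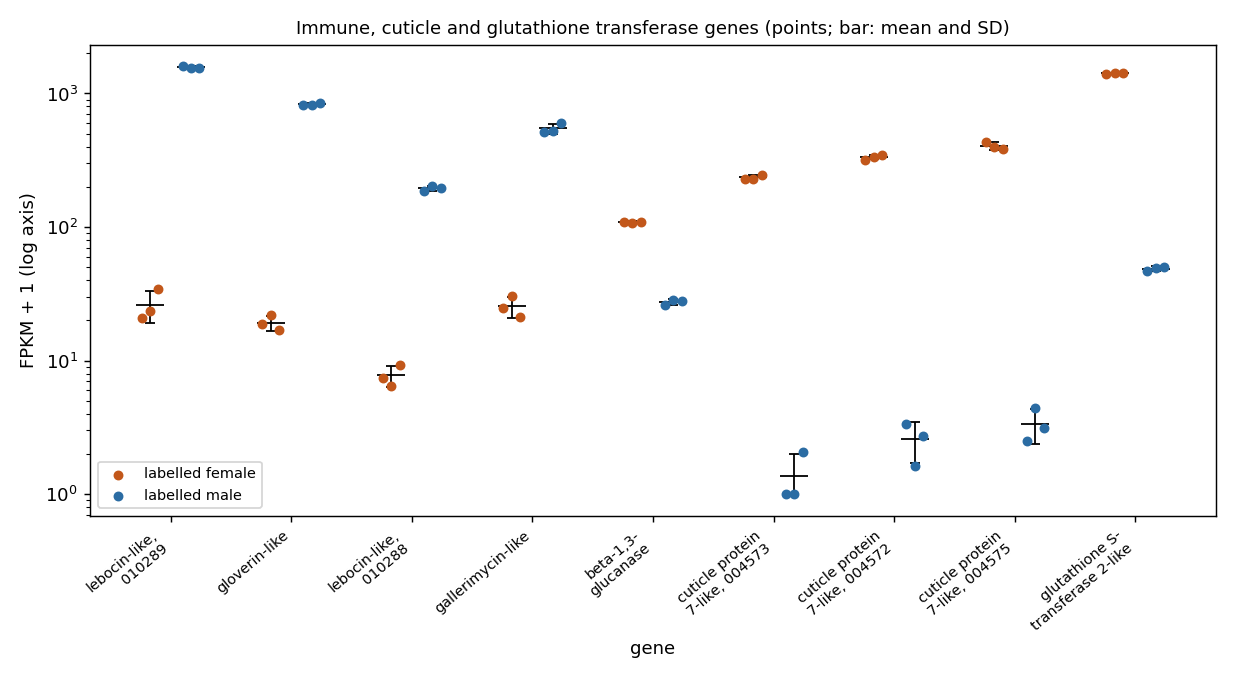
FPKM + 1 on a log axis for 5 genes of the immune list, 3 cuticle genes and 1 glutathione S-transferase gene, with a point per library, a bar at the mean and whiskers of 1 SD that end at 0 FPKM, for 3 libraries labelled female and 3 labelled male. The lebocin-like gene GWHGABGR010289 lies at a mean of 1575 FPKM in the male-labelled libraries and 25.2 in the female-labelled ones.

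Log2 fold changes of heat shock and ribosomal protein genes lay below those of other genes by camera. A pair of heat shock protein genes stood at 12.3 ± 3.8 against 0.658 ± 0.413 FPKM (GWHGABGR020796) and 10 ± 1.76 against 0.655 ± 0.446 FPKM (GWHGABGR020876). Of 43 tested heat shock proteins, 12 were higher in the male-labelled libraries and 19 in the female-labelled ones. The heat shock proteins gave 12 and 19 when adjusted over the list alone, and 2 and 21 after median-of-ratios rescaling. Their median was -0.03 and their mean -0.52 (camera adjusted p = 5.35e-05, and adjusted p = 0.0395 with an estimated correlation). Ribosomal protein S6 (GWHGABGR003787) stood at 1374 ± 22.6 against 824 ± 25.1 FPKM. Of 62 tested cytosolic ribosomal proteins, 5 were higher in the male-labelled libraries and 37 in the female-labelled ones. The cytosolic ribosomal proteins gave 6 and 40 when adjusted over the list alone, and 1 and 55 after median-of-ratios rescaling. Their median was -0.19 (camera adjusted p = 2.34e-17, and adjusted p = 0.0458 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.451; 1.09e-35 to 0.451 over all camera alternatives run).

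Cilia hold the olfactory receptors of sensory neurons. Intraflagellar transport protein 52 (GWHGABGR016781), which carries cargo along cilia, stood at 30.1 ± 0.677 against 13.9 ± 3.47 FPKM, and dynein regulatory complex protein 10-like (GWHGABGR011128) at 11.6 ± 3.69 against 31.1 ± 1.43 FPKM. Of 41 tested cilium and axoneme genes, 4 were higher in the male-labelled libraries and 12 in the female-labelled ones. The cilium and axoneme genes gave 4 and 13 when adjusted over the list alone, and 2 and 13 after median-of-ratios rescaling. Their median was -0.18 and camera placed them below other genes (adjusted p = 7.06e-04), a call that was lost with an estimated correlation (adjusted p = 0.0601 with an estimated correlation). Of 39 tested synapse and ion channel genes, 9 were higher in the male-labelled libraries and 4 in the female-labelled ones. The synapse and ion channel genes gave 9 and 4 when adjusted over the list alone, and 5 and 6 after median-of-ratios rescaling, with a camera adjusted p of 0.98. Syntaxin-1A (GWHGABGR010428) stood at 7.82 ± 0.358 against 17.4 ± 1.17 FPKM.

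Among the lists of other cell types and organs, those of muscle, eye, and ovary and testis did not pass camera, unlike the immune and cuticle lists above. Of 27 tested muscle genes, 2 were higher in the male-labelled libraries and 3 in the female-labelled ones. The muscle genes gave 2 and 2 when adjusted over the list alone, and 1 and 5 after median-of-ratios rescaling (camera adjusted p = 0.185). Muscle myosin heavy chain (GWHGABGR012005) stood at 2.45 ± 0.169 against 6.43 ± 0.648 FPKM. Of 13 tested eye genes, 5 were higher in the male-labelled libraries and 1 in the female-labelled ones. The eye genes gave 7 and 2 when adjusted over the list alone, and 2 and 2 after median-of-ratios rescaling (camera adjusted p = 0.699), with chaoptin (GWHGABGR002734) at 5.05 ± 0.697 against 14 ± 0.404 FPKM. Of 14 tested ovary and testis genes, 2 were higher in the male-labelled libraries and 1 in the female-labelled ones. The ovary and testis genes gave 2 and 1 when adjusted over the list alone, and 1 and 1 after median-of-ratios rescaling (camera adjusted p = 0.994). For ovary and testis and for synapse genes the medians (0.28 and 0.26) were positive and camera pointed down, and both medians were negative under quantile normalization (-0.05 and -0.01). For muscle the median was -0.01 and the mean 0.01.

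Signalling and metabolic lists did not pass camera on the deposited scale. Of 26 tested biogenic amine and neuropeptide genes, 6 were higher in the male-labelled libraries and 3 in the female-labelled ones. The biogenic amine and neuropeptide genes gave 6 and 3 when adjusted over the list alone, and 4 and 6 after median-of-ratios rescaling (camera adjusted p = 0.339). Their median was 0.16, their mean -0.04 and their median after rescaling -0.08. Of 35 tested hormone handling genes, 12 were higher in the male-labelled libraries and 4 in the female-labelled ones. The hormone handling genes gave 13 and 4 when adjusted over the list alone, and 7 and 8 after median-of-ratios rescaling (camera adjusted p = 0.517). Takeout-like genes went both ways, with GWHGABGR005070 at 22.5 ± 2.92 against 75.7 ± 3.99 FPKM and GWHGABGR014390 at 25.5 ± 3.79 against 4.42 ± 1.76 FPKM. Of 38 tested fatty acid and pheromone synthesis genes, 16 were higher in the male-labelled libraries and 6 in the female-labelled ones. The fatty acid and pheromone synthesis genes gave 16 and 6 when adjusted over the list alone, and 14 and 8 after median-of-ratios rescaling (camera adjusted p = 0.517). Of 36 tested respiratory chain genes, 6 were higher in the male-labelled libraries and 9 in the female-labelled ones. The respiratory chain genes gave 6 and 11 when adjusted over the list alone, and 3 and 22 after median-of-ratios rescaling. Their median was 0.02 and their mean 0.06, with camera pointing down (adjusted p = 0.067). After median-of-ratios rescaling the respiratory median was -0.24 and the list passed (adjusted p = 1.53e-06; 2.34e-07 to 0.75 over all camera alternatives run). It also passed without female replicate 3 (adjusted p = 0.0437) and without male replicate 3 (0.0491).

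The doublesex models had few reads. The model named female-specific doublesex isoform F2 (GWHGABGR017605) had 16 reads in the male-labelled libraries and 0 in the female-labelled ones, at least 6.2-fold higher (log2 fold change 1.40, SE 0.26, limma adjusted p = 0.00341). A model named male-specific doublesex isoform M (GWHGABGR017603) had 3 reads in the female-labelled libraries and 8 in the male-labelled ones, a ratio of 3.1 (exact 95% interval 0.744 to 18.1). It did not pass (limma adjusted p = 0.112), except without female replicate 2 (GWHGABGR017603 male-specific doublesex isoform M, adjusted p = 0.0192). Another isoform M model (GWHGABGR017606, 6 against 13 reads) lay below the filter, and fruitless (GWHGABGR002049, 6.3 ± 1.14 against 5.79 ± 0.107 FPKM) did not pass. Vitellogenin, the yolk precursor (GWHGABGR020830, chosen after its values were seen), had 29 reads in the male-labelled libraries and 0 in the female-labelled ones. Of 8 tested sex determination genes, 3 were higher in the male-labelled libraries and 0 in the female-labelled ones. The sex determination genes gave 4 and 0 when adjusted over the list alone, and 1 and 0 after median-of-ratios rescaling (camera adjusted p = 0.339). Of 8 tested circadian clock genes, 3 were higher in the male-labelled libraries and 0 in the female-labelled ones. The circadian clock genes gave 4 and 0 when adjusted over the list alone, and 3 and 1 after median-of-ratios rescaling (camera adjusted p = 0.339). This list passed with the 9 genes excluded by name put back (adjusted p = 0.0247, and 0.0222 by description only; 0.0222 to 0.437 over all camera alternatives run), so the outcome depends on exclusions made after names and some fold changes had been seen. Period (GWHGABGR000160) stood at 7.09 ± 1.21 against 13.4 ± 1.17 FPKM.

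**Figure D3:**
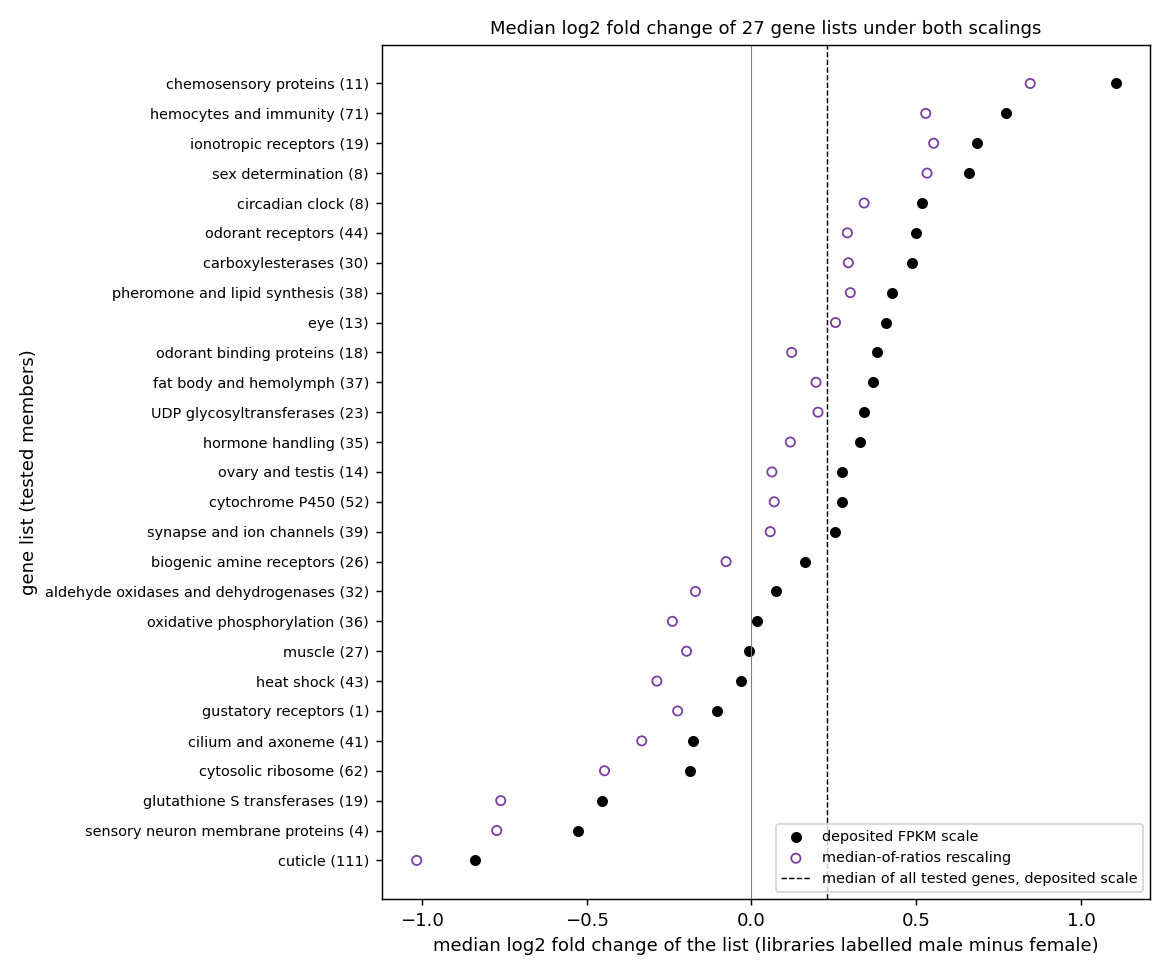
Median log2 fold change (libraries labelled male minus those labelled female) of the 27 gene lists on the deposited FPKM scale (filled points) and after median-of-ratios rescaling (open points), with the median of all tested genes on the deposited scale as a dashed line. The cuticle list lies at -0.84 and -1.02 and the immune list at 0.77 and 0.53, while the respiratory list passes from 0.02 to -0.24.

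On the deposited scale 8 of 25 lists passed camera with the preset correlation. With an estimated correlation 5 did, namely cuticle, immune genes, cytosolic ribosome, glutathione S-transferases and heat shock proteins. Among 303 pathways of the deposited annotation, Ribosome (camera adjusted p = 2.53e-09), Longevity regulating pathway - multiple species (1.62e-05) and Glycolysis / Gluconeogenesis (0.0193) had log2 fold changes below those of other genes. With an estimated correlation each had an adjusted p = 0.717.

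Shares of the summed signal were compared as well. Pheromone-binding protein 1 held 6.86 ± 0.123% against 0.0952 ± 0.0063% of total FPKM (SD, n = 3, female-labelled against male-labelled). Odorant-binding proteins together held 10.1 ± 0.136% against 3.31 ± 0.0887%, and with that gene set aside 3.21 ± 0.0171% against 3.21 ± 0.0844%. Their difference of -6.769 percentage points was -0.572 when the 10 most abundant genes, which include pheromone-binding protein 1 and general odorant-binding protein 2, were left out of both the list and the total. Odorant receptors held 0.119 ± 0.00261% against 0.0173 ± 0.00124%, of which olfactory receptor 1 held 0.0846 ± 0.00302% against 1.33e-05 ± 2.30e-05% and the others 0.0343 ± 5.77e-04% against 0.0173 ± 0.00124%. The 11 chemosensory proteins matched by name held 0.0872 ± 8.57e-04% against 0.179 ± 0.00227%. Outside that list, 6 genes with the symbol CG11390, which chemosensory protein 8 also carries, or with the name sensory protein 2 held 7.17 ± 0.0891% against 10.9 ± 0.0476%, so the printed share of chemosensory proteins may understate the family. These parts were chosen after seeing the data and were not tested. The cuticle list held 3.08 ± 0.0855% against 1.37 ± 0.0554% and the 10 most abundant genes 22.7 ± 0.225% against 23.2 ± 0.124%. Each of the differences for pheromone-binding protein 1, the 4 lists and the 10 most abundant genes had an exact permutation p = 0.1 (adjusted p = 0.111 over 30 comparisons), the smallest that 3 libraries against 3 allow.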

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

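The alternatives on recovered reads, on coding length and on list patterns were chosen after seeing the data; the others were planned. The number of genes past the test stayed within 1.5 times of 4274 under all settings except a threshold of at least 2-fold (1134, with 840 higher in the libraries labelled male and 294 in those labelled female, fewer by construction). The split moved with the scaling, from 3227 higher in the libraries labelled male and 1047 in those labelled female to 1652 and 2040 with median-of-ratios rescaling, 1636 and 1688 with quantile normalization, and 1888 and 2223 with limma-voom on recovered reads, since each removed most of the shift of the median gene. Without single replicates the count lay between 3460 and 3693 (2566 to 2739 and 877 to 954 by direction), and 6 to 11 lists passed. Of lists, 8 passed camera, 5 with an estimated correlation, 22 by fry and 25 by fry for changes either way, tests that do not compare a list with other genes. Where it passed, fry gave the other direction for muscle (median -0.007, adjusted p = 0.0104), odorant-binding proteins (0.381, 0.000127) and synapse genes (0.255, 0.00123). With a replicate block, 3845 genes passed (2891 and 954). Same-numbered libraries did not deviate together (correlations 0.00513, 0.00589 and -0.00375), so the numbers were not taken as pairs. Of 174 named genes with a fit, 125 kept their sign and side of the threshold under all alternatives run, and 10 changed sign only where they passed in neither fit. Of genes that passed in 1 or both fits, signs changed for ribosomal protein L18A GWHGABGR002819 (0.23 before, -0.03 with median-of-ratios rescaling and -0.03 with limma-voom), general odorant-binding protein 56a GWHGABGR017175 (0.00 before, -0.26 and -0.26), tyrosine hydroxylase GWHGABGR000528 (0.09 before, -0.16 and -0.16) and the unnamed GWHGABGR013872 (0.08 before, -0.18, -0.18 and, with quantile normalization, -0.53). Median-of-ratios rescaling, also used for the library sizes of limma-voom, shifts abundant genes alike, so small positive values turn negative by construction; the cause of the quantile value was not tested. The gap between the lowest correlation within a label and the highest across labels was 0.0324, 0.0404 with a pseudocount of 0.1 and 0.0455 with a mean FPKM of at least 2. The difference in share, male minus female, was -6.769 percentage points for odorant-binding proteins and -0.572 with the 10 most abundant genes left out of both list and total, and 0.091 and 0.12 for chemosensory proteins. Without single replicates these lay between -6.841 and -6.706 and between 0.09 and 0.092, and the difference for the 10 most abundant genes between 0.302 and 0.497. The planned edgeR quasi-likelihood test, meant as the main test for raw counts, and the planned DESeq2 alternative were not run, since both were tied to raw counts and the deposited unit is FPKM. Depth limits genes of few reads, such as the doublesex models.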

Other observations

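The tests of exchanged labels, of a single wrong label, of the most abundant genes, of hemocytes or fat body, of values under 2 FPKM and of other splits of the libraries were chosen after the results were seen; for those of the genes with the highest FPKM and of coding length, also added after the main results, the bounds were written before their values were seen. The most abundant genes given here were outside the rule for named genes and chosen after their values were seen. Among them, a circadian clock-controlled protein-like gene (GWHGABGR002941) stood at 25165 ± 861 FPKM (SD, n = 3) in the female-labelled libraries and 66560 ± 3591 in the male-labelled ones (log2 fold change 1.40, SE 0.04, limma adjusted p = 2.95e-08). Sensory protein 2 (GWHGABGR001105) stood at 24268 ± 838 against 48852 ± 145 FPKM and an uncharacterized gene with the symbol CG11390 (GWHGABGR001098) at 40843 ± 353 against 67397 ± 722 FPKM, both higher in the libraries labelled male, also with median-of-ratios and quantile scaling. A hypothetical protein gene (GWHGABGR001102, 19669.5 ± 428 against 9837 ± 129.8 FPKM) and heat shock protein cognate 4 (GWHGABGR010770, 14660.4 ± 206 against 11549 ± 332 FPKM) were higher in those labelled female.

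Pheromone-binding proteins 1 and 3 and olfactory receptor 1 were higher in the libraries labelled female and pheromone-degrading enzyme 1 in those labelled male (27 against 448 reads, limma adjusted p = 9.81e-06), and a candidate explanation of the former is that the labels of both sets are exchanged. By name, 4 genes called female-specific or vitellogenin had 49 reads in the libraries labelled male and 0 in those labelled female, which puts 100% of their reads, corrected for library totals, there (exact 95% interval 93.7 to 100%). Of reads of 5 genes called male-specific, 67.6% lay there too (62.2 to 72.6%), and 67.6% (58.2 to 76%) for the 3 that are not male-specific lethal models, whose name does not mean male-specific expression. Genes named microvitellogenin were not counted by this name pattern and went both ways. Microvitellogenin GWHGABGR016973 had 1 read in the libraries labelled female and 56 in those labelled male, and microvitellogenin-like GWHGABGR016997 had 890 and 567. Of the 4 male-named genes with a fit, male-specific lethal-3 GWHGABGR017403 passed on the deposited scale (limma adjusted p = 0.0388) and none after median-of-ratios rescaling (0.0993 to 0.277), and only 1 of the 4 female-named genes has a fit, so exchanged labels and a true sex difference cannot be told apart. A single wrong label is argued against, as the lowest correlation within a label (0.9844) exceeded the highest across labels (0.952), while a sex difference in the direction of the labels stays open.

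The median gene was 0.228 log2 units higher in the libraries labelled male. The most abundant genes are unlikely to be the whole cause, since without the 100 most abundant the median stayed at 0.179 (95% bootstrap interval over genes 0.168 to 0.189). Coding length is argued against by a difference of -0.005 between the 2892 longest and the 2921 shortest genes (-0.035 to 0.027). The bootstrap intervals here and below resample genes, which are not independent replicates, and do not cover the spread between libraries. Values under 2 FPKM are argued against as the whole cause, since the median stayed at 0.227 in the genes with a mean FPKM of at least 2 (0.216 to 0.239). The test of low depth over a wider range did not decide. The median was 0.082 in the 2898 genes with the highest mean FPKM (0.065 to 0.1), between the bounds of 0.05 and 0.1 set beforehand. It was 0.24, 0.33 and 0.268 in sets of like size below them. However, the libraries labelled female had more reads (10851262 to 11180175 against 9392242 to 9606755) yet fewer genes above 0 (13513 to 13651 against 13838 to 13869). The median also fell from 0.284 with a pseudocount of 0.1 to 0.128 with 5. These values argue against lower depth or the pseudocount as what raised the libraries labelled male. A difference in RNA content between the sexes was not tested.

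Immune effectors, 26 genes by name, had a median log2 fold change of 2.35, and RNA of hemocytes or fat body in the antennae labelled male may contribute. The median of 10 hemocyte markers lay 0.398 above that of all genes (95% bootstrap interval over genes 0.118 to 0.913). The median of 12 fat body proteins, 1 of them a vitellogenin receptor by name match, lay at -0.01 from that of all genes, with 9 values positive. Of the 12, 5 were called higher in the libraries labelled male and 1 in those labelled female (4 and 1 after median-of-ratios rescaling). The most abundant of the hemocyte markers, hemolin (GWHGABGR020071, chosen after its values were seen), stood at 1303 ± 38.9 against 2064 ± 66.5 FPKM. The interval reaches across the bound of 0.5 set for the markers, so a contribution of hemocytes cannot be told apart from a change within antennal cells, and hemolin is also an immune-induced gene. Coding length is argued against, since the immune list kept a median of 0.766 after its trend was removed (camera adjusted p = 1.82e-08).

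Other splits of the 6 libraries were counted for both main results. The real split gave 4274 genes by limma and the highest of the other splits 0 (5397 and 268 at an unadjusted p under 0.05). For lists, the real split gave 8 past camera and the highest other 5. In both cases 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. Every other split mixed the labels, so the difference between labels entered the spread within its groups and lowered its gene calls by construction. The gap in gene counts thus restates that the libraries separate by label.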
